A study of Mus musculus with 20 samples.

How the data were processed

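Gene expression was measured in the hypothalamus of diet-induced obese male C57BL/6J mice with 20 Affymetrix Mouse Gene 1.0 ST arrays. Per the labels' protocols, mice were 4 weeks old when a diet with 45% fat began and were fed it for 16 weeks. They were then injected into the peritoneum with celastrol, a triterpenoid from the thunder god vine, or with dimethyl sulfoxide (DMSO), its solvent and the vehicle control, and tissue was taken at 6 h, 1 day or 4 days. The labels give a volume of 25 µl of DMSO per day, and a celastrol dose of 250 µg/kg that stands beside the 6 h time alone. Total RNA was extracted with Trizol, cleaned on columns and labelled with biotin through the Ambion WT Expression kit, per the labels. The labels call the arrays of a group biological replicates. They name neither an array batch nor a scan or collection date, so no batch could be entered as a term.

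The authors deposited log2 intensities of 23492 probe sets, 1 column per array. The submitters' processing notes name RMA, which corrects background, quantile normalizes the arrays and summarises each probe set on the log2 scale. Its version, and the rule by which probe sets entered the deposited table, are not given in the sources used here. The median of an array lay between 8.60 and 8.65, and the SD over probe sets between 1.98 and 2.06. No pair of arrays held identical values. The platform annotation gave exactly 1 gene symbol for 20228 probe sets, several for 1399 and none for 1865, and 20182 of the single-symbol probe sets matched the mouse reference table by Entrez ID. Of 18704 genes with such a probe set, 809 had more than 1, and the brightest over all 20 arrays then stood for the gene. Probe sets below the 25th percentile of mean intensity, a log2 value of 7.04, were left out as dim, and 14129 genes were tested. Probe sets with several symbols or none entered no comparison between groups. For arrays, the number of arrays limits the precision, and with 3 or 4 per group the median standard error of a gene's log2 difference was 0.0605 to 0.0647.

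Differences were tested with limma 3.58.1 in R 4.3.3, in 1 linear model with a mean for each of the 6 groups, moderated by eBayes, with Benjamini-Hochberg adjustment over the 14129 genes and a threshold of 0.05. All groups shared 1 estimate of the spread, with 14 residual and 4.92 prior degrees of freedom. All tests were two-sided, and every adjusted p in the text comes from limma's moderated test for genes or from limma's camera for lists unless another tool is named. The comparisons were celastrol against DMSO at each time, the average over the times, the differences between times, and DMSO arrays between times. The test, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined.

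Of 35 fixed gene lists, 17 on biology and 18 on cell types or brain regions, 33 had at least 4 tested members and were tested with camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists. Camera was repeated with the correlation estimated from the data, and with that no list passed at any of the 3 times. Fry, which asks whether the members move one way on balance without comparing them with other genes, was run beside it. It called 0 lists at 6 h and at 4 days and 2 at 1 day, the glucocorticoid and leptin lists. Counts "adjusted over the list alone" apply the adjustment to the members of 1 list. Lists share members, among them Nfkbia (glucocorticoid and NF-kB), Per1 (glucocorticoid and circadian clock), Pdk4 and Plin4 (glucocorticoid and fatty acid oxidation), Dusp1 (glucocorticoid and immediate early), Gjb6 (glucocorticoid and astrocyte) and Socs3 (leptin and acute phase).

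Genes were named by a fixed rule. At each time these were, among genes past the threshold whose celastrol and DMSO arrays did not overlap, the 10 with the largest rise and the 10 with the largest fall. Where fewer than 5 passed in a direction, genes with the smallest unadjusted p filled it up to 5 and are given as not passing. Up to 4 members of each list with the smallest p were added, as were 10 genes fixed in advance, of which 7 were tested and the others were not analysed here. For the other comparisons the 5 genes with the smallest p in each direction were taken. Predicted genes counted but were not named. Genes named outside the rule are said to be.

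The procedure was tested on simulated data before use, with 5 runs of 200 changed genes among 14129. For a log2 change of 0.5 it recovered 95.5% of the changed genes in the 6 h comparison, 98.1% at 1 day and 96.5% at 4 days. For a change of 0.3 it recovered 73.5%, 71.4% and 70.4%. False calls made up 3.54%, 4.11% and 4.86% of all calls. The simulated noise was independent between genes. With 200 changed genes the adjusted threshold is also easier to pass than in the real comparisons, which called 0 genes at 6 h and 60 at 1 day. These shares therefore need not hold for the real arrays, and a count of 0 does not show that changes of this size were absent.

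Alternatives were other filters on dim genes, the mean of a gene's probe sets, arrays centred on their medians or quantile normalized again, another variance model, array weights, fits to the compared groups alone, the replicate number as a block, marker means of neighbouring regions or choroid plexus as a covariate, a minimum of 1.5-fold, and leaving out each array in turn. A covariate for the SD of each array, a fit without 2 vehicle arrays that stood apart, and both rescalings for the gene lists were added after seeing the data. Plots were drawn in Python 3.11.15 with matplotlib 3.10.9.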

Results

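The series holds 20 hypothalamus arrays from diet-induced obese mice. Vehicle (DMSO) was measured on 3 arrays at each of 6 h, 1 day and 4 days, and celastrol on 4 arrays at 6 h, 4 at 1 day and 3 at 4 days. Values are log2 intensities, and differences are celastrol minus DMSO on the log2 scale, with their standard errors. Of the arrays, vehicle replicate 3 at 6 h and vehicle replicate 3 at 1 day stood apart from their groups, with scores of 11.4 and 9.61 on the leading component of the residuals against -6.13 to 5.32 for all others.

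The comparison at 1 day asked which hypothalamic transcripts differed between 4 celastrol and 3 vehicle arrays after 1 day. Celastrol arrays had higher levels of genes that glucocorticoids induce, and of several NF-kB and acute phase genes, and lower levels of Cldn5, Fabp7, Pax6 and the connexin genes Gjc3 and Gjb1. Among genes past the threshold, the largest rise was in Ch25h, which makes 25-hydroxycholesterol, from 6.69 ± 0.22 (SD, n = 3) to 8.12 ± 0.43 (SD, n = 4), a log2 difference of 1.42 ± 0.23 or 2.68-fold (limma adjusted p = 0.00743). The vehicle level of Ch25h lay below 7.04, the level under which genes were left out as dim, so this fold change starts from a low signal. Sgk1, a kinase induced by glucocorticoids, rose from 9.51 ± 0.22 to 10.67 ± 0.055, or 2.24-fold (limma adjusted p = 0.000236). The largest fall among them was in Cldn5, the main claudin of endothelial tight junctions in brain, from 10.19 ± 0.12 to 9.57 ± 0.15, a level 1.53-fold lower (limma adjusted p = 0.00857). The Ch25h call ended without vehicle replicate 2 at 1 day (adjusted p = 0.0568) and the Cldn5 call without vehicle replicate 1 (0.0794).

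In all, 60 of 14129 genes passed the threshold at 1 day, 51 higher and 9 lower, and 17 of them differed at least 1.5-fold. All 60 had celastrol and vehicle arrays that did not overlap. Over all genes 7.81% did not overlap, against 5.71% by chance. The division into higher and lower moved with the scaling, to 33 and 17 with arrays centred on their medians and to 43 and 18 with arrays quantile normalized again. The count was 18 without vehicle replicate 1 at 1 day, 19 without vehicle replicate 2, 23 without vehicle replicate 3, 26 without celastrol replicate 3 and 30 without celastrol replicate 2, and it was 196 with array weights.

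The glucocorticoid target list moved as a group at 1 day. All 19 of its tested members were higher, with a median of 0.61, and 10 passed over all genes (17 adjusted over the list alone). Besides Sgk1, the members that rose included Nfkbia, which encodes the inhibitor that holds NF-kB in the cytoplasm (0.93 ± 0.12, limma adjusted p = 0.000986), Ddit4, an inhibitor of mTOR signalling (0.68 ± 0.11, limma adjusted p = 0.005), and Per1, a clock gene that glucocorticoids also induce (0.29 ± 0.050, limma adjusted p = 0.0124). Fkbp5, a co-chaperone of the glucocorticoid receptor, rose by 0.88 ± 0.17 (limma adjusted p = 0.0256), a call that ended without any 1 of the 3 vehicle arrays or celastrol replicates 2 and 3 of 1 day, at 0.0716 to 0.143. That of Per1 ended without vehicle replicate 1 (0.0807) or 3 (0.0716). Camera gave the list an adjusted p = 1.59e-30, and adjusted p = 0.098 with an estimated correlation. Fry gave an adjusted p = 0.00816. Its mean over members was 10.40 ± 0.059 (SD, n = 4) in celastrol and 9.84 ± 0.060 (SD, n = 3) in vehicle arrays at 1 day.

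The acute phase and NF-kB lists were higher at 1 day with smaller medians, the interferon list was lower and the interleukin-1 family list did not pass. In the acute phase and STAT3 list, 13 of 16 members were higher, 2 passed over all genes and 4 adjusted over the list alone. Osmr, the receptor subunit for oncostatin M, rose by 1.19 ± 0.22 (limma adjusted p = 0.0168) and Serpina3n, a protease inhibitor of reactive astrocytes, by 0.32 ± 0.070 (limma adjusted p = 0.0456), while Lcn2 differed by 1.61 ± 0.56 and did not pass (limma adjusted p = 0.379). In the NF-kB and cytokine list, 10 of 15 were higher, 3 passed over all genes, and adjusted over the list alone 4 were higher and 1 lower. The 3 were Ch25h, Nfkbia and Ptgs2, the inducible cyclooxygenase, which rose by 1.03 ± 0.14 (limma adjusted p = 0.00243), while Ccl7, a chemokine, differed by -0.21 ± 0.056 (limma adjusted p = 0.144). The acute phase list had a median of 0.152 and the NF-kB list of 0.0778. Camera's adjusted p was 0.000164 for the acute phase list (adjusted p = 0.242 with an estimated correlation) and 0.013 for the NF-kB list (adjusted p = 0.266 with an estimated correlation). Without vehicle replicate 3 at 1 day, which stood apart, these became 0.0968, with a median of 0.0886, and 0.179. With no filter on dim genes the NF-kB list had a median of 0.0117 and an adjusted p = 0.168. The Serpina3n call ended without any 1 of 13 of the 20 arrays, at up to 0.333, and with arrays centred or no filter. The Osmr call ended without any 1 of the 3 vehicle arrays or celastrol replicate 3 of 1 day, at 0.0685 to 0.0768. The interferon response list was lower (13 of 16, median -0.102, none passing, adjusted p = 0.0103, and adjusted p = 0.242 with an estimated correlation), with a median of -0.0355 and an adjusted p = 0.318 without the same array, and medians of -0.156 and -0.155 without vehicle replicates 1 and 2. The interleukin-1 family list did not pass (median 0.0616, adjusted p = 0.433).

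The leptin signalling list was higher at 1 day, in 13 of 18 members with a median of 0.0831 (camera adjusted p = 0.00397, and adjusted p = 0.242 with an estimated correlation). Fry gave it an adjusted p = 0.0499. None of its members passed, over all genes or adjusted over the list alone. The leptin receptor gene Lepr differed by 0.17 ± 0.064 (limma adjusted p = 0.416) and Ptpn1, a phosphatase that dampens leptin signalling, by 0.14 ± 0.053 (limma adjusted p = 0.409). Without vehicle replicate 3 at 1 day the list had an adjusted p = 0.0502. Among genes of feeding circuits, Mc4r, the melanocortin receptor through which satiety signals act, rose by 0.26 ± 0.053 (limma adjusted p = 0.0353). That call was lost without any 1 of the 3 vehicle arrays of 1 day or of celastrol replicates 2, 3 and 4, at an adjusted p of 0.0841 to 0.129, and also under both rescalings. Pomc (-0.14 ± 0.14), Npy (0.069 ± 0.093) and Socs3 (0.12 ± 0.088) did not pass. The anorexigenic (median -0.00929, adjusted p = 0.584) and orexigenic lists (0.0454, adjusted p = 0.584) did not pass.

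Metabolic and stress lists moved little at 1 day. Fatty acid oxidation and fasting genes were higher in 11 of 15 members (median 0.0414, adjusted p = 0.0348, and adjusted p = 0.266 with an estimated correlation). Over all genes none passed, and adjusted over the list alone 4 were higher, among them Ppara and Txnip, and 1 lower, Acot2, with differences of 0.26 ± 0.061, 0.61 ± 0.15 and -0.28 ± 0.076. The circadian clock list was higher in 12 of 16 (median 0.0657, adjusted p = 0.0261, and adjusted p = 0.274 with an estimated correlation), with Per1 passing. Proteasome subunits were higher in 24 of 28 (median 0.0443, adjusted p = 0.0431, and adjusted p = 0.658 with an estimated correlation), with none passing. Heat shock genes, chaperones induced by protein damage, were lower in 14 of 18 (median -0.0393, adjusted p = 0.0316, and adjusted p = 0.469 with an estimated correlation), with none passing. Without vehicle replicate 1 at 1 day the adjusted p was 0.0777 for fatty acid oxidation, 0.206 for the clock, 0.248 for the proteasome and 0.171 for heat shock. Other single arrays also ended these calls, namely vehicle replicate 3 for fatty acid oxidation (0.0968), the proteasome (0.0502) and heat shock (0.0564), celastrol replicate 1 (0.0541) or 2 (0.132) for fatty acid oxidation, celastrol replicate 4 for the clock (0.131), and for the proteasome vehicle replicate 2 at 6 h (0.0531) and at 1 day (0.0564), celastrol replicates 1 (0.0521), 2 (0.0825) and 3 (0.456) at 1 day and celastrol replicate 3 at 4 days (0.0529). With arrays quantile normalized again these 4 calls ended too, at 0.0746 for fatty acid oxidation and the clock and 0.0526 for the proteasome and heat shock, and the proteasome call also with arrays centred (0.0554). Medians moved as well. Without vehicle replicate 1 at 1 day they were 0.0223 for fatty acid oxidation, 0.0337 for the clock, 0.0214 for the proteasome and -0.0106 for heat shock. Without celastrol replicates 2 and 3 fatty acid oxidation had 0.0224 and 0.0268, without vehicle replicate 3 the clock had 0.103, without celastrol replicates 3 and 4 the proteasome had 0.0109 and 0.0795, and without celastrol replicate 4 heat shock had -0.0234. With arrays centred they were 0.0155, 0.0398, 0.0184 and -0.0652 in the same order, and fatty acid oxidation had 0.0148 with arrays quantile normalized again and 0.0246 with no filter. Heat shock did not pass with no filter on dim genes (0.0822), the proteasome with region markers as a covariate (0.0543), and with array SD as a covariate the clock (0.0807), fatty acid oxidation (0.0729) and the proteasome (0.123). Hspa5 and Hmox1, markers of endoplasmic reticulum and oxidative stress, differed by -0.026 ± 0.061 and 0.0021 ± 0.067. No shift was called for the unfolded protein response (adjusted p = 0.81), NRF2 targets (0.806), immediate early genes (0.506), cholesterol biosynthesis (0.291) or oxidative phosphorylation (0.234).

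Among cell type lists at 1 day, oligodendrocyte markers were lower in 10 of 12 genes (median -0.17, adjusted p = 7.92e-05, and adjusted p = 0.242 with an estimated correlation). 1 gene passed over all genes and 2 adjusted over the list alone. Gjc3, a connexin of myelinating glia, fell by 0.30 (SE 0.055, limma adjusted p = 0.0192), Opalin differed by -0.59 ± 0.18 without passing, and the myelin genes Mbp and Mobp differed by -0.027 ± 0.037 and 0.11 ± 0.057. Astrocyte markers were lower in 9 of 13 (median -0.0255, adjusted p = 0.0206, and adjusted p = 0.242 with an estimated correlation), with Sox9 passing at -0.24 ± 0.052. Pan-neuronal markers were lower in 14 of 16 (median -0.0462, adjusted p = 0.0255, and adjusted p = 0.266 with an estimated correlation). Pituitary markers were lower in 7 of 7 (median -0.136, adjusted p = 0.0234, and adjusted p = 0.266 with an estimated correlation). Ependymal and tanycyte markers were higher in 11 of 13 (median 0.0782, adjusted p = 0.00879, and adjusted p = 0.242 with an estimated correlation), with Dio2, the enzyme that activates thyroid hormone in tanycytes, at 0.50 ± 0.11 (limma adjusted p = 0.0423). Without vehicle replicate 3 at 1 day the adjusted p was 0.106 for astrocytes, 0.151 for neurons and 0.0968 for ependymal cells. It was 0.0507 for astrocytes and 0.206 for the pituitary without vehicle replicate 1, and 0.0696 for neurons without celastrol replicate 3. With arrays quantile normalized again the astrocyte (0.0552), neuronal (0.0854) and pituitary (0.0526) calls ended, the last also with arrays centred (0.0782) or array SD as a covariate (0.0521). The astrocyte median was -0.0644, -0.0396 and -0.0424 without vehicle replicates 2 and 3 and celastrol replicate 2 and -0.0513 with arrays centred, which gave neurons -0.0721, and the pituitary median was -0.0371 and -0.214 without vehicle replicates 1 and 3. With no filter on dim genes the neuronal (0.0647) and pituitary (0.233) calls ended. The Dio2 call stayed in 4 and the Sox9 call in 5 of the 20 fits without 1 array, with adjusted p up to 0.185 and 0.202, and both ended with no filter, as did that of Dio2 with arrays centred. The Gjc3 call stayed in 15 of the 20. The oligodendrocyte and glucocorticoid calls stayed with each single array left out and under both rescalings.

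Endothelial genes went both ways at 1 day. Cldn5 fell while Slc2a1, the glucose transporter of the blood-brain barrier, rose by 0.48 ± 0.092 (limma adjusted p = 0.0205), and adjusted over the list alone 3 were higher and 2 lower. The endothelial list had a median of 0.032 and a mean of -0.00727 (adjusted p = 0.807). No shift was called for oligodendrocyte precursors (adjusted p = 0.177), microglia (0.721), macrophages (0.164, or 0.0438 with arrays quantile normalized again), mural cells (0.685), choroid plexus (0.177), meningeal fibroblasts (0.338), hypothalamic nuclei (0.584), thalamus (0.691), striatum (0.184), or cortex and hippocampus (0.177). In the striatum list Gpr6, an orphan receptor, passed at 0.63 ± 0.094 (limma adjusted p = 0.00406).

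Other genes that rose at 1 day were Acer2, an alkaline ceramidase (0.88 ± 0.11, or 0.37 with the mean of its probe sets), Plekhf1 (0.76 ± 0.12), Scgb3a1, a secretoglobin (1.17 ± 0.25), and Sult1a1, a sulfotransferase (0.70 ± 0.15). Fabp7, a fatty acid binding protein of radial glia and astrocytes, fell from 12.62 ± 0.092 (SD, n = 3) to 12.05 ± 0.075 (SD, n = 4), by 0.57 (SE 0.067, limma adjusted p = 0.000486). Pax6, a transcription factor of neural progenitors, fell by 0.39 (SE 0.068, limma adjusted p = 0.0121). Falls were smaller in Map6d1 (-0.32 ± 0.060), Creb5 (-0.28 ± 0.056), Insc (-0.28 ± 0.046) and Gjb1, a connexin of oligodendrocytes (-0.25 ± 0.053). The calls of Scgb3a1, Sult1a1 and Gjb1 stayed in 6, 7 and 8 of the 20 fits without 1 array and ended with no filter on dim genes and with arrays centred. Of 26 named genes past the threshold, 8 stayed past it with each of the 20 arrays left out in turn, namely Sgk1, Nfkbia, Acer2, Ddit4, Fabp7, Gpr6, Plekhf1 and Ptgs2. Of the 26, 16 were lost without vehicle replicate 1 of 1 day, 15 without vehicle replicate 2, 14 without vehicle replicate 3 and 13 without celastrol replicate 3. The sign of all 60 genes stayed in each of those fits, but this was fixed in advance, since their celastrol and vehicle arrays did not overlap.

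**Figure D1:**
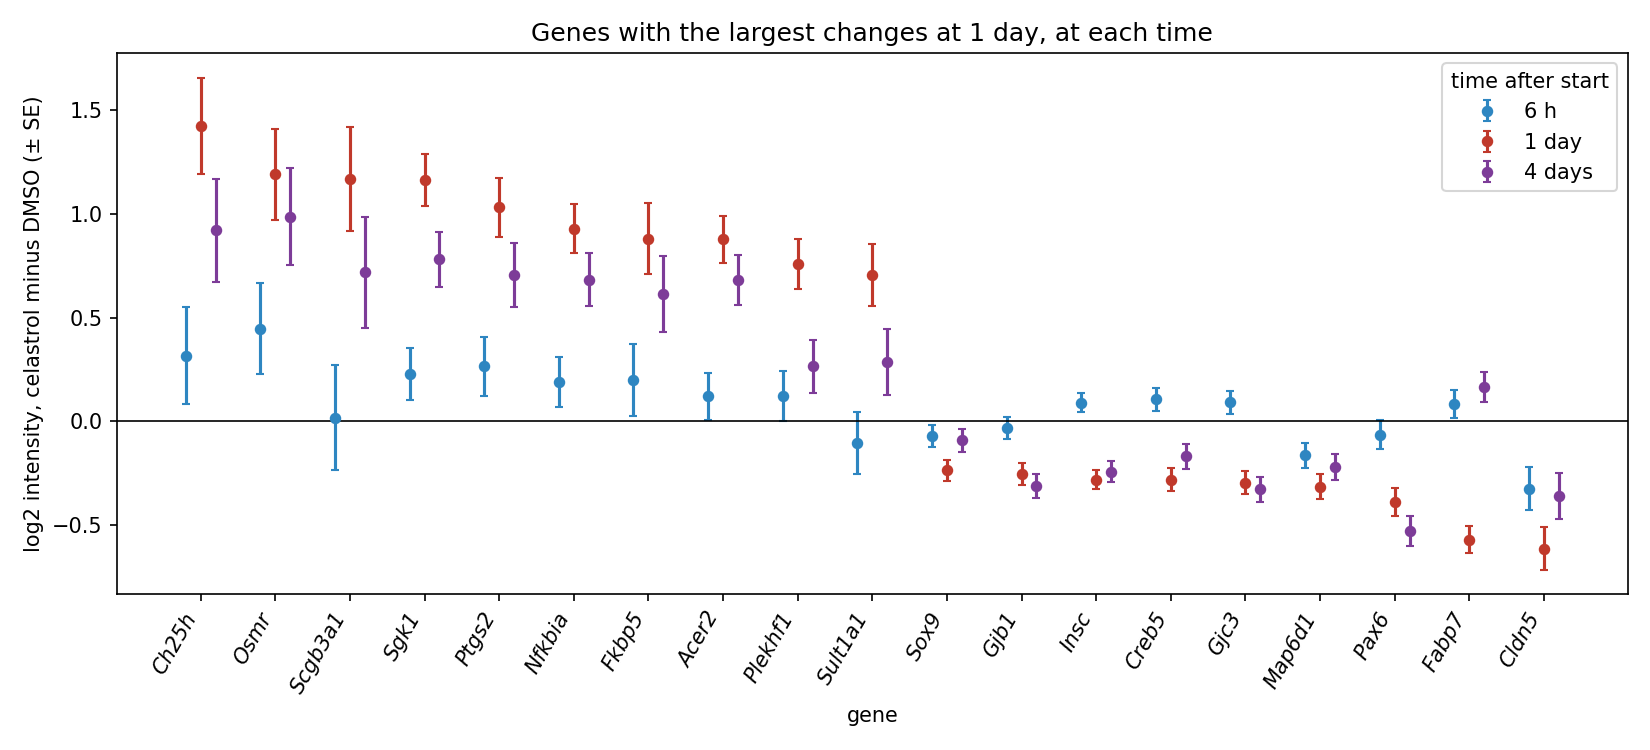
Log2 difference in intensity, celastrol minus DMSO, on the vertical axis for 19 genes past the threshold at 1 day. They are the 10 named genes with the largest rise and the 9 genes that fell. Points are given at 6 h, 1 day and 4 days, with bars of 1 standard error. Ch25h reached 1.42 at 1 day, and the 10 genes on the left were higher at 1 day and at 4 days.

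The comparison at 4 days asked which transcripts differed after 4 days, with 3 celastrol and 3 vehicle arrays. Fewer genes passed than at 1 day, with Sgk1 and Acer2 again higher and Pax6, Gjc3 and Gjb1 again lower. Pax6 fell from 8.52 ± 0.060 (SD, n = 3) to 7.99 ± 0.10 (SD, n = 3), a level 1.44-fold lower (limma adjusted p = 0.00948). Sgk1 rose from 9.76 ± 0.24 to 10.54 ± 0.19, or 1.72-fold, and Acer2 rose 1.60-fold (limma adjusted p = 0.0413 for both), though with the mean of its probe sets Acer2 differed by 0.36 and did not pass (adjusted p = 0.141). Fyb, an adaptor protein of leukocytes, rose by 0.42 ± 0.066 (limma adjusted p = 0.0257). Csf3r, the receptor for granulocyte colony-stimulating factor, rose by 0.30 ± 0.050, Cyp4f15, a cytochrome P450 of fatty acid metabolism, by 0.40 ± 0.071, and Pla2g4e, a phospholipase, by 0.31 ± 0.054.

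At 4 days 9 genes passed, 6 higher and 3 lower, and 2 of them differed at least 1.5-fold. All 9 had groups that did not overlap. Over all genes 14.4% did not, against 10% by chance. The division was 1 higher and 2 lower with arrays centred on their medians, and 3 and 3 with arrays quantile normalized again. The connexins fell by 0.33 (Gjc3, SE 0.059) and 0.31 (Gjb1, SE 0.057). Insc (-0.24 ± 0.049, limma adjusted p = 0.0938) and Efna1 (-0.35 ± 0.075, limma adjusted p = 0.146) came next and did not pass. The count at 4 days rested on single arrays. It was 0 without vehicle replicate 2 at 4 days, and 1 without vehicle replicate 1 or celastrol replicate 3 of that time. It was 2 without vehicle replicate 3 at 4 days, vehicle replicate 1 or 2 at 1 day, celastrol replicate 1 or 2 at 6 h, or any 1 of the 4 celastrol arrays at 1 day. It was 3 without celastrol replicate 2 at 4 days, 15 without vehicle replicate 1 at 6 h and 20 without celastrol replicate 1 at 4 days. None of the 9 stayed past the threshold with each array left out.

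Glucocorticoid targets were higher at 4 days in 19 of 19 genes, with a median of 0.343, 1 gene passing over all genes and 10 adjusted over the list alone (camera adjusted p = 3.67e-19, and adjusted p = 0.218 with an estimated correlation). Ddit4 (0.61 ± 0.11) and Nfkbia (0.68 ± 0.13) had limma adjusted p = 0.0501 each. The acute phase list was higher in 14 of 16 (median 0.156, adjusted p = 1.17e-05, and adjusted p = 0.228 with an estimated correlation), with 4 genes adjusted over the list alone. Lcn2, an acute phase lipocalin, differed by 2.36 ± 0.60 without passing (limma adjusted p = 0.287). The leptin signalling list was higher in 13 of 18 (median 0.0803, adjusted p = 0.00993, and adjusted p = 0.228 with an estimated correlation), with none adjusted over the list alone. Oligodendrocyte markers were lower in 11 of 12 (median -0.225, adjusted p = 2.8e-09, and adjusted p = 0.218 with an estimated correlation), with 3 adjusted over the list alone. The glucocorticoid, acute phase and oligodendrocyte calls stayed with each single array left out, but without celastrol replicate 3 at 4 days the glucocorticoid median was 0.164 and the oligodendrocyte median -0.139. The list mean of glucocorticoid targets in celastrol arrays at 4 days had an SD of 0.306 (n = 3). The leptin call ended without vehicle replicate 3 (adjusted p = 0.128) or celastrol replicate 3 (0.0667) at 4 days. Fry called none of these lists, with adjusted p = 0.0925 for the glucocorticoid, leptin and oligodendrocyte lists and 0.112 for the acute phase list.

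Weaker shifts at 4 days were higher NF-kB targets (9 of 15, median 0.0571, adjusted p = 0.0371, and adjusted p = 0.548 with an estimated correlation) and clock genes (10 of 16, median 0.0377, adjusted p = 0.0371, and adjusted p = 0.548 with an estimated correlation). Heat shock genes were lower in 15 of 18 (median -0.0559, adjusted p = 0.0146, and adjusted p = 0.548 with an estimated correlation), and the unfolded protein response in 16 of 26 (median -0.036, adjusted p = 0.0371, and adjusted p = 0.548 with an estimated correlation). None of their genes passed over all genes. Each call ended without a single array of that time. Without vehicle replicate 3 the adjusted p was 0.267 for NF-kB, whose median was then -0.00113, 0.072 for the clock and 0.0998 for the unfolded protein response. Without vehicle replicate 1 it was 0.115 for the clock, 0.331 for heat shock and 0.153 for the unfolded protein response. Without celastrol replicate 2 it was 0.13, 0.144 and 0.144 for those same lists, without celastrol replicate 3 it was 0.187 for NF-kB, and without celastrol replicate 1 it was 0.0868 for the clock. With arrays quantile normalized again it was 0.0689 for the clock, and with array SD as a covariate 0.0934. Medians were -0.0218 for heat shock, -0.0197 for the unfolded protein response and 0.0164 for the clock without vehicle replicate 1, -0.0238 for heat shock without celastrol replicate 2, and 0.0953 and 0.0321 for NF-kB without celastrol replicates 1 and 3. For the clock it was 0.0207 with arrays centred and 0.0214 with arrays quantile normalized again. With no filter on dim genes the adjusted p was 0.152 for NF-kB (median 0.0106) and 0.0676 for the unfolded protein response. The other 25 lists at 4 days had adjusted p-values of at least 0.0529, the lowest for cholesterol biosynthesis (median -0.0556), which passed with arrays centred (0.0328) or quantile normalized again (0.0142). Immediate early genes passed with the latter (0.0386), and choroid plexus with no filter on dim genes (0.019). Lepr (0.13 ± 0.068), Ptpn1 (0.13 ± 0.056), Pomc (-0.17 ± 0.15), Npy (0.17 ± 0.10), Socs3 (0.15 ± 0.094), Hspa5 (-0.079 ± 0.066) and Hmox1 (0.015 ± 0.071) did not pass.

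**Figure D2:**
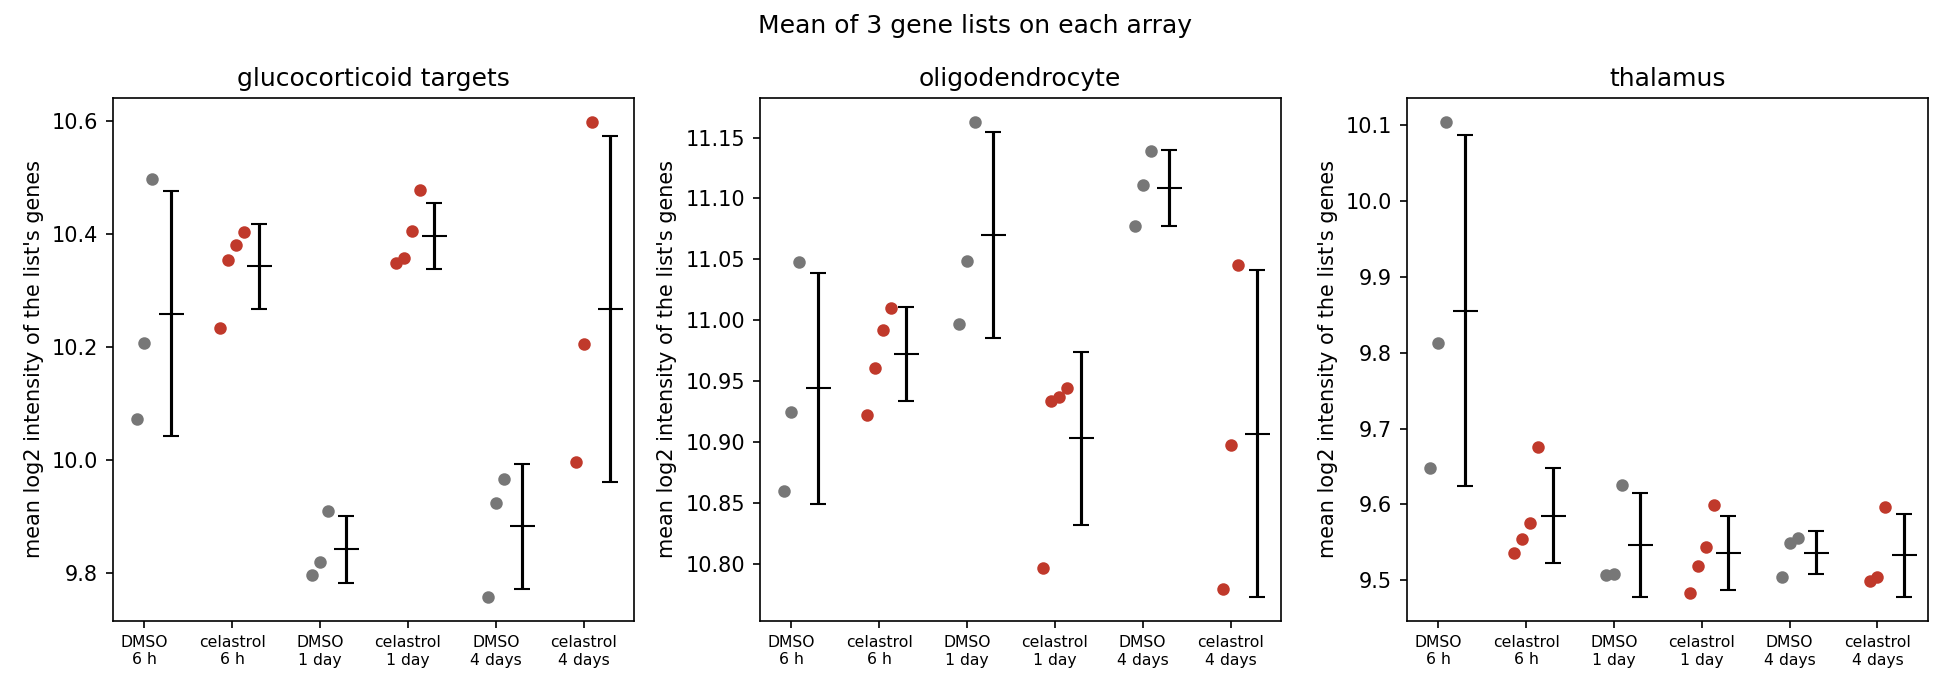
Mean log2 intensity of the genes of the glucocorticoid target, oligodendrocyte and thalamus lists on the vertical axis, 1 point per array in each of the 6 groups, with the group mean and bars of 1 SD beside the points. Glucocorticoid targets averaged 10.40 in celastrol and 9.84 in vehicle arrays at 1 day, and 10.26 in vehicle arrays at 6 h.

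The comparison at 6 h asked which transcripts differed at the earliest time, with 4 celastrol and 3 vehicle arrays. No single gene passed. Limma called 0 genes, and the smallest adjusted p was 0.431. An unadjusted p under 0.05 was found for 1067 genes, where 706 would be expected had no gene changed. Genes that vary together can move such counts either way, so the excess does not show changed genes. For the difference between 1 day and 4 days the count was 349. Every alternative filter, scaling, variance model and covariate also gave 0. Without vehicle replicate 2 at 6 h, 6 genes passed, all lower. The genes with the smallest p were higher in Sctr, the secretin receptor (0.29 ± 0.058), Hoxb13 (0.29 ± 0.067), Sncg (0.24 ± 0.053), CK137956 (0.23 ± 0.051) and Mylk (0.20 ± 0.050). They were lower in Rora (-0.31 ± 0.066), Hirip3 (-0.26 ± 0.059), Ercc8 (-0.25 ± 0.053), Riok2 (-0.24 ± 0.056) and Zfp266 (-0.22 ± 0.045), with limma adjusted p = 0.431 for each. Lepr (-0.020 ± 0.064), Pomc (0.087 ± 0.14), Npy (-0.0078 ± 0.093), Socs3 (0.085 ± 0.088), Ptpn1 (-0.0077 ± 0.053), Hspa5 (-0.0084 ± 0.061) and Hmox1 (-0.032 ± 0.067) did not pass.

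At 6 h camera called 7 lists at the preset correlation and 0 with an estimated one, and fry called 0. Of the 35 splits of the 7 arrays, 4 gave as many lists. Thalamus markers were lower in 9 of 10 genes, with a median of -0.26 and 8 genes adjusted over the list alone (camera adjusted p = 5.14e-07, and adjusted p = 0.427 with an estimated correlation). Prkcd, a kinase enriched in thalamic relay neurons, differed by -0.79 ± 0.20 (limma adjusted p = 0.431), and Plekhg1 by -0.40 ± 0.12. The list averaged 9.85 ± 0.23 (SD, n = 3) in vehicle arrays at 6 h and 9.59 ± 0.063 (SD, n = 4) in celastrol arrays at 6 h, beside 9.53 to 9.55 in the later groups. Beside this difference in thalamus markers, NF-kB and cytokine targets were higher in 14 of 15 genes (median 0.099, adjusted p = 0.000305, and adjusted p = 0.433 with an estimated correlation), with none adjusted over the list alone, Ptgs2 at 0.26 ± 0.14 and Nfkbia at 0.19 ± 0.12. Both calls stayed with each single array left out and under both rescalings, but without vehicle replicate 3 at 6 h, which stood apart, the thalamus median was -0.137 and the NF-kB median 0.0657. The NF-kB median was also 0.0438 with region markers and 0.059 with array SD as a covariate and 0.0561 with arrays quantile normalized again, and the thalamus call ended with region markers as a covariate (adjusted p = 0.575), which holds these genes.

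Lists with smaller medians at 6 h were higher for the glucocorticoid (15 of 19, median 0.0726, adjusted p = 0.0191, and adjusted p = 0.728 with an estimated correlation), acute phase (9 of 16, median 0.0854, adjusted p = 0.0195, and adjusted p = 0.686 with an estimated correlation) and immediate early lists (16 of 20, median 0.0369, adjusted p = 0.0207, and adjusted p = 0.686 with an estimated correlation). Klf4 was the immediate early gene with the smallest p (0.25 ± 0.071). Pituitary markers (7 of 7, median 0.0614, and adjusted p = 0.686 with an estimated correlation) and meningeal fibroblast markers (8 of 9, median 0.137, and adjusted p = 0.728 with an estimated correlation) were higher too, at adjusted p = 0.0446 each. The glucocorticoid list had a median of -0.0208 and an adjusted p = 0.672 without vehicle replicate 1 at 6 h, and the acute phase list one of -0.0081 and 0.462. Without vehicle replicate 2 the medians were 0.164 and 0.216, and 0.162 for the pituitary list. The pituitary median was 0.137 and 0.0959 without celastrol replicates 1 and 3, and that of immediate early genes 0.0586 without celastrol replicate 1 or 2 and 0.00755 without replicate 4. The glucocorticoid and acute phase calls also ended without vehicle replicate 3 (0.0841 for both) and without celastrol replicate 2 (0.0511 and 0.136) or 3 (0.0558 and 0.0695). The immediate early call ended without vehicle replicate 2 (0.114) or celastrol replicate 2 (0.0511) or 4 (0.0983). At 6 h the pituitary call ended without vehicle replicate 1 (0.0968) or 3 (0.374) or celastrol replicate 2 (0.114) or 4 (0.27, median -0.00624), and the meningeal call without vehicle replicate 2 (0.172) or 3 (0.278, median 0.0514) or celastrol replicate 2 (0.163, median 0.0912), 3 (0.0558) or 4 (0.0983). Both also ended without celastrol replicate 3 at 1 day (0.0537 and 0.0532) or celastrol replicate 1 at 4 days (0.0505 for both), and the pituitary call without celastrol replicate 4 at 1 day (0.0507). Of these 5 lists none passed with arrays centred (0.057 to 0.189), and only the glucocorticoid list did with arrays quantile normalized again. With no filter on dim genes only the acute phase list passed (the others 0.0617 to 0.122), with array SD as a covariate none (0.0808 to 0.644, with a median of -0.0312 for the pituitary list), and with region markers as one the acute phase (0.173), pituitary (0.509) and meningeal lists (0.173) did not. With array SD as a covariate the meningeal median was 0.0659, that of the acute phase list 0.0536 and that of immediate early genes 0.0243, and with region markers they were 0.0835, 4.33e-05 and 0.0645. The acute phase median was 0.041 without vehicle replicate 3 and 0.0418 without celastrol replicate 3, that of immediate early genes 0.0666 with arrays centred, and that of the pituitary list 0.0979 with arrays quantile normalized again. The other 26 lists at 6 h had adjusted p-values of at least 0.0886, with medians from -0.0616 to 0.0506, and of them cholesterol biosynthesis passed with no filter on dim genes (0.034).

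Median, mean and camera's direction differed in sign for 5 lists at 6 h, 6 at 1 day and 7 at 4 days, of which 0 were called. They included the anorexigenic list at all 3 times, hypothalamic nuclei and choroid plexus at 6 h and 1 day, microglia at 1 day and 4 days, and the cortex and hippocampus list at 6 h and 4 days.

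The average over the 3 times asked which genes differed in the mean of the 3 effects. A gene can pass it through some of the times only, so passing does not show a change at each time. At 6 h alone limma called 0 genes. Sgk1 (0.72 ± 0.074), Ptgs2 (0.67 ± 0.085), Nfkbia (0.60 ± 0.071), Acer2 (0.56 ± 0.067, or 0.26 with the mean of its probe sets) and Gpr6 (0.40 ± 0.056) had the smallest p among genes that rose. Cldn5 (-0.43 ± 0.061), Slc40a1, the iron exporter ferroportin (-0.36 ± 0.062), Pax6 (-0.33 ± 0.040), Map6d1 (-0.23 ± 0.035) and Gjb1 (-0.20 ± 0.031) had the smallest p among genes that fell, and limma's adjusted p was at most 0.0081 for these 10. All 10 stayed past the threshold with each array left out. In all 81 genes passed, 60 higher and 21 lower, and 5 of them differed at least 1.5-fold. The count was 39 without vehicle replicate 1 at 4 days, 44 without celastrol replicate 3 at 4 days, 46 and 51 without vehicle replicates 1 and 2 at 1 day, 51 without vehicle replicate 1 at 6 h, 53 without vehicle replicate 3 at 4 days, 133 without celastrol replicate 1 at 4 days and 156 without vehicle replicate 2 at 6 h. It was 35 with region markers as a covariate and 39 without both vehicle arrays that stood apart. Glucocorticoid targets were higher in 19 of 19 genes, with a median of 0.311 and 9 passing (camera adjusted p = 7.79e-34, and adjusted p = 0.0661 with an estimated correlation).

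Differences between times were tested as interactions. The effect on Fabp7 at 1 day differed from that at 6 h by -0.66 ± 0.095 (limma adjusted p = 0.0201) and its effect at 4 days from that at 1 day by 0.74 ± 0.098 (limma adjusted p = 0.00631). The effect at 4 days exceeded that at 6 h in Fyb (0.59 ± 0.090, limma adjusted p = 0.0361) and Cyp4f15 (0.60 ± 0.097, limma adjusted p = 0.0453). Those were the only genes past the threshold, 1 between 6 h and 1 day, 2 between 6 h and 4 days and 1 between 1 day and 4 days. Sgk1 differed between 6 h and 1 day by 0.94 ± 0.18 without passing (limma adjusted p = 0.147). With arrays quantile normalized again, 3 higher and 1 lower passed between 6 h and 4 days. The Fabp7 difference between 1 day and 4 days stayed past the threshold with each array left out. The count between 6 h and 1 day went to 0 without any 1 of 8 arrays and to 3 without celastrol replicate 3 at 6 h, and that between 6 h and 4 days to 0 without any 1 of 12 arrays, as listed in the closing section.

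Across genes, which are not independent replicates, the effects at 1 day and 4 days had a correlation of 0.485 (Spearman 0.328), with no arrays shared. Those at 6 h correlated at -0.0957 with 1 day and -0.0562 with 4 days. Of the 51 genes that rose at 1 day, 51 had a positive difference at 4 days, 41 of them at an unadjusted p under 0.05 and 3 past the threshold. At 6 h 39 had a positive difference, 4 of them at an unadjusted p under 0.05.

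Vehicle arrays were compared between times as the background of the time course. From 6 h to 1 day, Sgk1 fell by 0.94 (SE 0.13, limma adjusted p = 0.00779), the cardiac actin gene Actc1 by 1.54 (SE 0.24, limma adjusted p = 0.0186) and the cardiac myosin gene Myh6 by 0.57 (SE 0.097, limma adjusted p = 0.0244), and Morc4 and Mb21d2 fell by 0.31 and 0.27. Wdr83os rose by 0.58 ± 0.062 (limma adjusted p = 0.000214), Acot2 by 0.49 ± 0.082, and Kcnip3, Sncg and Ankzf1 by 0.32, 0.30 and 0.21. From 6 h to 4 days, Wdr83os rose by 0.65 ± 0.062 (limma adjusted p = 3.14e-05), Sncg rose by 0.33, and Actc1 and Myh6 fell by 1.57 and 0.63. Glucocorticoid targets were lower in 18 of 19 genes at 1 day than at 6 h (median -0.44, camera adjusted p = 8.27e-15, and adjusted p = 0.284 with an estimated correlation) and in 19 of 19 at 4 days (median -0.351, adjusted p = 1.9e-14, and adjusted p = 0.453 with an estimated correlation). Thalamus markers were lower in 9 of 10 genes (median -0.294, adjusted p = 1.27e-06, and adjusted p = 0.282 with an estimated correlation) and in 10 of 10 (median -0.253, adjusted p = 1.91e-07, and adjusted p = 0.406 with an estimated correlation). The thalamus list mean had an SD of 0.231 in vehicle arrays at 6 h, where replicate 3 stood apart, against 0.068 at 1 day and 0.0283 at 4 days. For the glucocorticoid list mean the SD was 0.217 at 6 h, against 0.06 at 1 day and 0.11 at 4 days. List differences between vehicle arrays were not repeated with single arrays left out.

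Between vehicle arrays, 14 genes passed from 6 h to 1 day, 5 higher and 9 lower, which was 32 higher and 15 lower with arrays centred on their medians and 26 and 20 with arrays quantile normalized again. From 6 h to 4 days 4 genes passed, 2 higher and 2 lower. From 1 day to 4 days limma called 0 genes, with 1041 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0802, while 147 passed with array weights. These counts moved with single arrays, from 1 to 47 and from 1 to 18 for the comparisons with 6 h, and the arrays are named in the closing section. Of the named genes, Wdr83os alone stayed past the threshold in both with each array left out.

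**Figure D3:**
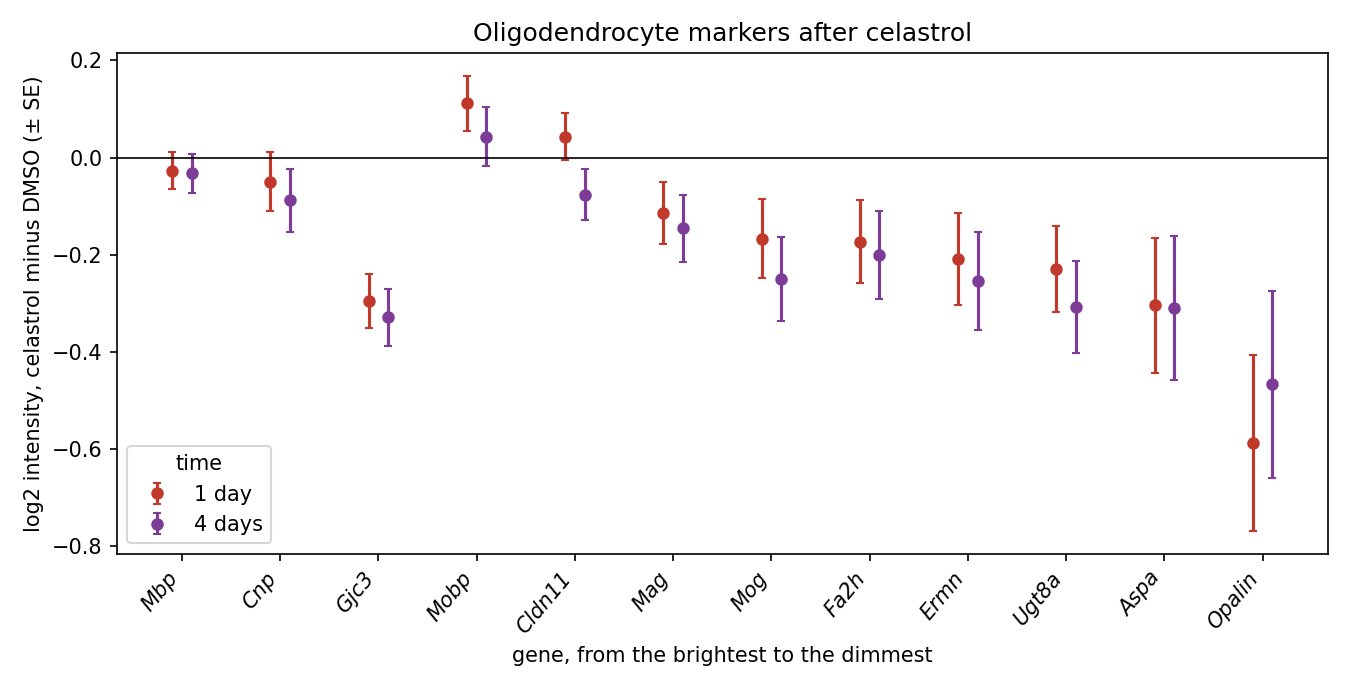
Log2 difference in intensity, celastrol minus DMSO, on the vertical axis for the 12 oligodendrocyte markers in order of brightness, at 1 day and 4 days, with bars of 1 standard error. Gjc3 lay at -0.30 and -0.33 and passed at both times, while Mobp lay at 0.11 and 0.043.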

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

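The tests chosen only after the result was seen were those of vehicle arrays already high at 6 h, of more thalamus in the 6 h dissections of celastrol and of vehicle mice, of a separate batch at 6 h and of oligodendrocyte numbers, and the covariate for array dynamic range as a setting. The margin of 1 SE for the clock genes and that for the oligodendrocyte test were also set after their values were seen.

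Glucocorticoid targets were higher after celastrol at 1 day, and their effect at 1 day exceeded that at 6 h by a median of 0.556 (camera adjusted p = 3.3e-11, and adjusted p = 0.473 with an estimated correlation). The tables argue against array dynamic range and against neighbouring brain regions as the whole cause of the rise at 1 day, since its median was 0.624 with the SD of each array as a covariate and 0.613 with region markers as one, against 0.612 without. The difference between times goes with the vehicle arrays, in which the list was lower at 1 day than at 6 h by a median of -0.44 (18 of 19 genes), while the celastrol means were 10.34 at 6 h and 10.40 at 1 day. The list mean varied widely over the 3 vehicle arrays at 6 h, with an SD of 0.217 against 0.06 at 1 day. The vehicle difference was not repeated with single arrays left out. Collection of the vehicle mice at different times of day found no sign in Dbp, Nr1d1, Arntl and Ciart, which differed by at most 0.147 in size between these arrays (Ciart, -0.147 ± 0.0825). That lies inside the bound of 0.3 set beforehand by more than 1 SE, a margin set afterwards. At 2 SE Ciart reaches past the bound, so different times of day are made less likely but not ruled out. A response to celastrol, and handling or injection at 6 h, which was not tested, both stay open as hypotheses.

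Vehicle arrays at 6 h stood apart from later ones in Wdr83os, Actc1 and Myh6, and so did celastrol arrays in Wdr83os (-0.355 ± 0.0534 against 1 day and -0.515 ± 0.0576 against 4 days), in Actc1 and, against 1 day, in Myh6 (0.453 ± 0.0843), which did not pass against 4 days (0.371 ± 0.091, adjusted p = 0.0546). In celastrol arrays there was little sign of more thalamus in the 6 h dissections. The thalamus list was higher at 6 h than at 1 day by a median of 0.0588, in 7 of 10 genes, while Actc1 differed by 1.09 ± 0.212. A small excess is not excluded, since Prkcd was higher at 6 h by 0.24 ± 0.18, without passing (limma adjusted p = 0.512). More thalamus stays open for vehicle arrays, where the list was higher at 6 h than at 1 day by a median of 0.294. That difference leans on vehicle replicate 3 at 6 h, which stood apart. Without it the celastrol difference of the list at 6 h went from a median of -0.26 to -0.137. Over all 6 h arrays against all later ones the list was higher by 0.143 in 9 of 10 genes and Prkcd by 0.665 ± 0.121 (adjusted p = 0.00882). In that comparison 431 genes differed, 136 higher and 295 lower at 6 h. A separate array or collection batch and the time itself cannot be told apart, because no label gives a batch and every 6 h array differs from the later ones in time as well.

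Oligodendrocyte markers were lower after celastrol at 1 day, by a median of -0.17. Changes ranged from -0.588 (Opalin) to 0.112 (Mobp) and correlated at 0.771 with brightness across the 12 members. Their spread around the trend with brightness was 0.118, and 1 of the 35 splits of the 7 arrays gave one as large, the real one, with 0.113 as the next, while a plain SD of the changes, tried before it, was 0.185, also 1 of 35, with 0.166 as the next. Neither decides, since the margin is narrow and the other splits hold no fall that bright or less specific markers could pass on unequally. Fewer oligodendrocytes in the celastrol samples and a change in expression within these cells both stay open.

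In groups of 4 arrays, 128 values were tested for an array far from the others, by Dixon's ratio of the gap to the range at its 95% critical value, and 6 exceeded it where chance gives 6.4, or 1 in 20. They were Cyp4f15 at 1 day (0.875, replicate 3), Dio2 at 1 day (0.842, replicate 3), Pla2g4e at 1 day (0.86, replicate 4), Ptgs2 at 6 h (0.904, replicate 3), the mean of the astrocyte list at 1 day (0.89, replicate 4) and that of the oligodendrocyte list at 1 day (0.929, replicate 4), each in celastrol arrays.

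Effects of celastrol differed between times by limma's interaction test in Fabp7 (-0.655 from 6 h to 1 day and 0.736 from 1 day to 4 days), Fyb (0.593) and Cyp4f15 (0.597, both from 6 h to 4 days). From 6 h to 1 day the effect on lists differed for glucocorticoid targets (0.556, adjusted p = 3.3e-11), interferon response (-0.118, 0.0081), circadian clock (0.117, 0.0221), proteasome (0.0908, 0.0254), oligodendrocyte (-0.171, 0.000306), pituitary (-0.206, 0.00389) and thalamus (0.301, 0.00389), and with an estimated correlation the adjusted p was 0.473 or higher for each. From 6 h to 4 days it differed for glucocorticoid targets (0.255, 1.13e-05), circadian clock (0.107, 0.017), oligodendrocyte (-0.231, 4.23e-07), pituitary (-0.248, 0.0158), meningeal fibroblast (-0.247, 0.0158) and thalamus (0.267, 0.00197), with 0.5 or higher. From 1 day to 4 days it differed for glucocorticoid targets (-0.102, 0.00494) and oxidative phosphorylation (-0.0505, 0.0492), at 0.888 for both with an estimated correlation.

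Among 2204 probe sets with several gene symbols or none, which entered no comparison, 2 passed at 1 day, both higher after celastrol, with 129 at an unadjusted p under 0.05. At 6 h and at 4 days limma called 0 of them, with 106 and 84 at an unadjusted p under 0.05.

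Other splits of the same arrays into groups of the same sizes were fitted beside the real one. The share of splits with a count as large was under 0.05 for the genes at 1 day (60 genes, and 1 of 35 splits as many, with 1 gene as the highest other). It was so for the average too (81, 1 of 100, highest other 4), and chance is unlikely for both. For the lists at 1 day (14, 1 of 35) the share was also under 0.05. There, another split reached 12 and no list held with an estimated correlation, so that count is not well set apart from chance. The share was also under 0.05 for the differences between 6 h and 4 days (2, 4 of 100), but another split gave 3, more than the real one, and the count went to 0 without any 1 of 12 arrays. For the genes at 6 h the count of 0 is reached by any split (35 of 35), which decides nothing. Another split gave 17, the cause of which was not tested. Chance is not excluded for the lists at 6 h (7, 4 of 35, highest other 8), for the differences between 6 h and 1 day (1, 7 of 100, highest other 8) or those between 1 day and 4 days (1, 5 of 100, highest other 2). The 10 splits were too few for a share under 0.05 for the genes at 4 days (9, 1 of 10, highest other 0), the lists at 4 days (8, 3 of 10, highest other 11), and vehicle arrays from 6 h to 1 day (14, 2 of 10, highest other 19), from 6 h to 4 days (4, 1 of 10, highest other 0) and from 1 day to 4 days (a count of 0, so 10 of 10, highest other 2).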

How the results depend on the processing

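The covariate for array dynamic range, the fit without both vehicle arrays that stood apart and the rescalings of the lists were chosen after seeing the data. The 6 h count of genes was 0 under every setting but 1 left-out array, and all 29 called lists kept their direction under both rescalings, with 7 calls lost by centring and 12 by quantile normalization. Of the counts that moved by over 1.5 times the cause was not tested, except where fewer arrays or a stricter threshold made it. With 3 or 4 arrays per group and a median standard error of 0.0605 to 0.0647, small changes could go uncalled. Whether dim genes are limited further by their signal over background was not tested.

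The mean of the probe sets of a gene moved Acer2 alone among the named calls by over 1.5 times. With no filter on dim genes, 10 of the 29 list calls ended, as given in the report, 2 genes passed at 4 days, 0 differed between 6 h and 4 days, and 24 between vehicle arrays at 6 h and 1 day. A filter at the 50th percentile gave 2 for the difference between 6 h and 1 day, 1 between 6 h and 4 days, and 63 and 30 for vehicle arrays at 1 day and 4 days against 6 h. Arrays centred on their medians gave 3 at 4 days, 0 between 6 h and 4 days, 47 and 7 for vehicle against 6 h, and 2 lists at 6 h. Quantile normalized again, arrays gave 4 between 6 h and 4 days, 46 and 14 for vehicle against 6 h, and 3 lists at 6 h and 8 at 1 day. Trend and robust variance gave 3 at 4 days, 3 between 6 h and 1 day, 79 and 40 for vehicle against 6 h and 4 for vehicle from 1 day to 4 days. Array weights gave 196 at 1 day, 20 at 4 days, 2 between 6 h and 1 day, 24 for vehicle from 6 h to 1 day and 147 from 1 day to 4 days. With arrays of the compared groups only, 2 passed at 4 days and 0 for the differences of 6 h from 1 day and from 4 days and for vehicle at both times against 6 h. Neighbouring regions as a covariate gave 2 at 4 days, 35 on average, and 0 for those same 4 comparisons, and turned the heat shock list at 6 h to 0.0491 (adjusted p = 0.0194). Choroid plexus as a covariate gave 3 at 4 days and 0 between 6 h and 4 days. At least 1.5-fold left 17 at 1 day, 2 at 4 days, 5 on average and 4 for vehicle from 6 h to 1 day. Camera with estimated correlation gave 0 lists at each time, and fry 0, 2 and 0. Array dynamic range as a covariate gave 0 between 6 h and 4 days, 137 and 45 for vehicle against 6 h, 4 from 1 day to 4 days and 4 lists at 6 h. Without both vehicle arrays that stood apart, 39 passed on average, 0 between 6 h and 4 days, 1 for vehicle at each time against 6 h, and 4 lists at 1 day and 5 at 4 days.

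Within a time, replicate numbers gave little sign of pairing vehicle with celastrol arrays. Deviations of vehicle and celastrol arrays with the same number correlated at -0.17, 0.29 and -0.12 at 6 h, -0.29, -0.0063 and -0.29 at 1 day and -0.061, -0.042 and -0.017 at 4 days, and 1 of 9 correlated best with its own number. Numbers were not compared across times in this way. On the leading component of the residuals, celastrol replicate 1 scored highest in its group at 6 h, 1 day and 4 days (4.72, 5.32 and 4.67). Vehicle replicate 3 did so at 6 h and 1 day (11.4 and 9.61) but not at 4 days (0.134). Something shared by a number across times is therefore not excluded. The replicate block within each time gave 32 genes at 1 day (24 of the 60), 3 at 4 days, 35 on average, 0, 1 and 0 for the differences of 6 h from 1 day, 6 h from 4 days and 1 day from 4 days, and 4 lists at 6 h. Celastrol replicate 4 at 6 h and at 1 day had no vehicle array of its number, so this block in effect left it out. It also left fewer residual degrees of freedom. Lower counts under it are therefore no sign of pairing. The replicate block across times gave 0 for the differences of 6 h from 1 day and from 4 days and 1 for vehicle from 6 h to 4 days.

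Leaving out single arrays gave 0 to 6 genes at 6 h, 18 to 85 at 1 day, 0 to 20 at 4 days and 39 to 156 on average. Differences between 6 h and 1 day ranged from 0 to 3, with 0 without vehicle replicate 1 or 2 or celastrol replicate 2 or 4 at 6 h, or vehicle replicate 2 or 3 or celastrol replicate 3 or 4 at 1 day. Those between 6 h and 4 days ranged from 0 to 3, with 0 without vehicle replicate 2 or 3 or celastrol replicate 1, 2 or 4 at 6 h, vehicle replicate 1 or 2 or celastrol replicate 1 or 4 at 1 day, or vehicle replicate 2 or 3 or celastrol replicate 3 at 4 days, 3 without vehicle replicate 3 at 1 day and 1 without 6 further arrays. The difference between 1 day and 4 days stayed at 1. Vehicle arrays from 6 h to 1 day gave 1 to 47: 1 without vehicle replicate 3 at 6 h or 1 day, 4 and 5 without vehicle replicates 1 and 2 at 1 day, 9 without vehicle replicate 2 or 3 at 4 days, 25 without vehicle replicate 1 at 6 h or celastrol replicate 3 at 1 day, 38 without celastrol replicate 3 at 4 days and 47 without vehicle replicate 2 at 6 h. From 6 h to 4 days they gave 1 to 18: 1 without vehicle replicate 3 at 6 h or 2 or 3 at 4 days, 2 without vehicle replicate 1 at 4 days, 7, 11 and 8 without celastrol replicates 1, 2 and 3 at 6 h, 14 and 16 without vehicle replicates 1 and 2 at 6 h, and 12 and 18 without celastrol replicates 1 and 3 at 4 days. From 1 day to 4 days they gave 0 to 1, the latter without celastrol replicate 3 at 4 days. Lists ranged from 2 to 9 at 6 h (2 without celastrol replicate 2, 4 without replicate 3 or 4), 4 to 15 at 1 day (4 without vehicle replicate 3) and 4 to 10 at 4 days (4 and 5 without vehicle replicates 3 and 1).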

Other observations

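Averaged over the 3 times, further lists were shifted by camera. Higher were acute phase and STAT3 targets (14 of 16, median 0.122, adjusted p = 3.05e-09, and adjusted p = 0.0661 with an estimated correlation), leptin signalling (15 of 18, median 0.0619, adjusted p = 0.000112, and 0.0661), NF-kB and cytokine targets (11 of 15, median 0.0356, adjusted p = 1.14e-05, and 0.117) and ependymal and tanycyte markers (12 of 13, median 0.0361, adjusted p = 0.00348, and 0.149). Lower were oligodendrocyte markers (median -0.122, adjusted p = 3.89e-06, and adjusted p = 0.179 with an estimated correlation), thalamus markers (median -0.0901, adjusted p = 0.00135, and 0.284) and cholesterol biosynthesis (14 of 18, median -0.033, adjusted p = 0.00527, and 0.284). In the last no gene passed. The thalamus list mean differed mainly at 6 h, at 9.85 in vehicle arrays, where replicate 3 stood apart, and 9.59 in celastrol arrays. It was 9.55 and 9.54 at 1 day and 9.54 and 9.53 at 4 days, in the same order. The oligodendrocyte list mean was not lower after celastrol at 6 h (10.94 in vehicle and 10.97 in celastrol arrays). List calls on the average were not repeated with single arrays left out.

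Macrophage and monocyte markers were higher in 5 of 5 genes at 1 day, with a median of 0.159 that did not pass (adjusted p = 0.164). In vehicle arrays, interferon response genes were higher at 1 day than at 6 h in 15 of 16 (median 0.136, adjusted p = 0.000374, and adjusted p = 0.282 with an estimated correlation). The list mean was 8.63 (SD 0.0881) in vehicle arrays at 1 day and 8.47 to 8.56 in the other groups. The lower list after celastrol at 1 day uses the same vehicle arrays, so it is not a separate observation.

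Comparisons that use the same vehicle arrays share their chance values. The celastrol effect at 1 day correlated across genes with the vehicle change from 6 h to 1 day at -0.537, against -0.536 in 100 simulations with no effect, with a covariance of -0.00537 against -0.00288. Of the 51 genes that rose at 1 day, 51 were lower in vehicle arrays at 1 day than at 6 h, where simulations gave 46 to 51. Against vehicle arrays at 4 days, which that effect does not use, 50 of the 51 were lower than at 6 h, where simulations gave 18 to 36 and 52.7% of all genes were lower. The simulations drew each gene independently. Genes that vary together could give counts far outside these ranges by chance, so the ranges do not decide whether chance explains the 50.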
